A study of Mus musculus with 18 samples.

How the data were processed

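Whole larynges of male C57BL6/J mice were profiled by mRNA sequencing in 18 libraries, 6 each from mice exposed to room air, to smoke of 3R4F research cigarettes and to aerosol of JUUL Virginia tobacco e-cigarettes. Per the labels' protocols, total RNA was extracted with a column kit, and 1 µg per sample went into an NEBNext Ultra RNA library kit, which does not mark strand. Per the submitters' processing notes, STAR (version not given) and featureCounts 1.5.0-p3 were used, with the builds GRCm38 and mm10. The annotation release and the strand setting of the counting are not given in the sources used here. Without strand, reads from a gene and its antisense partner cannot be told apart. Overlapping genes and near-identical paralogs, such as Hspa1a and Hspa1b, Bpifb9a and its neighbouring copy, and the Mup, Smr and Gstm families, have uncertain counts for the same reason that reads can be split between copies.

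The deposited table holds raw counts, whole numbers per gene and library, with gene coordinates that are quoted here as deposited. It lists 54532 genes, of which 35370 had at least 1 count. A reference annotation of the same build (GENCODE M21) held 54495 of these identifiers, 53585 with the same start and end. Each column name matched the title of 1 sample, and no column was left unmapped. The labels do not say that each library is 1 animal, so p-values measure only the spread between these samples. Pairs of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom 16.9 to 150 over 45 pairs), and the sex-linked transcripts of 18 of 18 libraries matched the male label. The labels name no lane, day or batch.

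Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 17537 genes, 15213 of them protein coding. The 3 groups were fitted in 1 model without covariates in edgeR 4.0.16 (TMM factors, robust quasi-likelihood fit, R 4.3.3), and each pair of groups was compared with the quasi-likelihood F test. The p-values were adjusted by Benjamini-Hochberg over the tested genes, and "called", "rose" and "fell" mean an adjusted p below 0.05. Unless another tool is named, adjusted p-values of genes are from this edgeR fit. Fold changes are log2 values, standard errors (SE) derive from the F statistic, and CPM means counts scaled to 1 M per library with TMM-scaled library sizes. A group with 0 counts was bounded with a floor of 3 counts over the group, and a group with 1 to 3 counts is given as a ratio with an exact 95% counting interval. Both cover counting error only.

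Gene lists were fixed from the tissue and the exposures, 44 in number, naming 1000 symbols, of which 995 were found and 908 were tested. The 43 lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes. Beside it stand camera with an estimated correlation and fry, adjusted over the 43 lists. No list call held with an estimated correlation in any comparison. The Fast skeletal muscle, Cartilage, Thyroid and Adipocytes lists served also as composition scores, and the Glandular acini list was added to them later.

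The comparisons, tests, lists, alternatives and naming rule were chosen before the data were examined. The rule took, per comparison, the 10 largest positive and 10 largest negative log2 fold changes among called protein-coding genes with a mean of at least 1 CPM in at least 1 of the groups compared and the same sign in every fit without 1 library. Symbols starting with Gm and a digit or ending in Rik, and immunoglobulin and T cell receptor segments, were left out. It also took up to 3 called members with the smallest p from each list, of which the text leaves out part (1 of them is not reported here), and 15 fixed genes whatever their p. These were Cyp1a1, Cyp1b1, Ahrr, Tiparp, Nqo1, Gclc, Hmox1, Il1b, Il6, Muc5ac, Muc5b, Krt5, Krt13, Foxj1 and Scgb1a1. Of these, Il6 had too few counts to be tested. Tg, Lipf, Acan and Adipoq were singled out outside this rule, after their values were seen, as was Calca in e-cigarette versus air. Pth, and Calca in smoke versus e-cigarette, were also taken by the rule.

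The edgeR step was tested on simulated counts for 17330 genes. It recovered 25.0% of genes changed 1.5-fold, 76.6% of those changed 2-fold and 97.1% of those changed 4-fold in smoke versus air, and 39.7%, 78.3% and 94.8% in e-cigarette versus air, with 9 unchanged genes called in each. These counts were drawn independently per gene, so differences in tissue content that many genes share were not simulated. The rates may therefore not hold for the real libraries. Alternatives were DESeq2 1.42.0, voom with sample quality weights, other scalings and filters, fits of only 2 groups, a block for replicate number, composition covariates, surrogate variables (sva 3.50.0), stricter thresholds and leaving out each library. Leaving out sets of libraries by their thyroid, gland or cartilage transcripts, a thyroid score alone and 5 instead of 4 covariates were added after the data were seen.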

Results

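Larynx transcriptomes were measured after 4 weeks of exposure in a whole-body inhalation chamber, for 1 hour a day on 5 days of each week. The mice were males of the inbred C57BL6/J strain, 8 to 9 weeks old. Groups of 6 libraries came from mice kept in room air, exposed to smoke of the 3R4F research cigarette, or exposed to aerosol of JUUL Virginia tobacco e-cigarettes. The study set out to compare the larynx's transcriptional response to each exposure with air and with the other. Total counts were 15.6 to 17.1 M per library in air, 15.9 to 20.3 M in smoke and 16.7 to 22.5 M in e-cigarette. Libraries detected 23735 to 26788 genes, and 17537 genes were tested. The mitochondrial genome gave 4.18% to 6.09% of counts in air, 4.66% to 5.19% in smoke and 4.97% to 7.60% in e-cigarette. Coordinates are those of the deposited table (GRCm38, mm10).

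Transcripts of tissues that adjoin or line the larynx varied between libraries. Tg (ENSMUSG00000053469, chromosome 15, 66670753 to 66850721), which encodes thyroglobulin of thyroid follicles, took 6.13% to 10.2% of counts in air and 5.87% to 9.24% in smoke. In e-cigarette libraries 1 to 6 it took 2.69%, 0.0729%, 2.77%, 0.00854%, 0.00795% and 0.271%. Calca (ENSMUSG00000030669, chromosome 7, 114631478 to 114636357), the calcitonin gene of thyroid C cells, was at 1764 ± 634 CPM in air, 1130 ± 231 CPM in smoke and 82.6 ± 116 CPM in e-cigarette (SD, n = 6 each). Within the air group, replicates 4, 5 and 6 stood apart. The lipase gene Lipf was at 3247, 623 and 1168 CPM there against 13702 to 21291 CPM in air 1, 2 and 3, and the cartilage proteoglycan gene Acan was at 17.6, 6.09 and 7.01 CPM against 83.2 to 141 CPM. The first principal component held 31.8% of the variance and the second 16.3%.

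**Figure D1:**
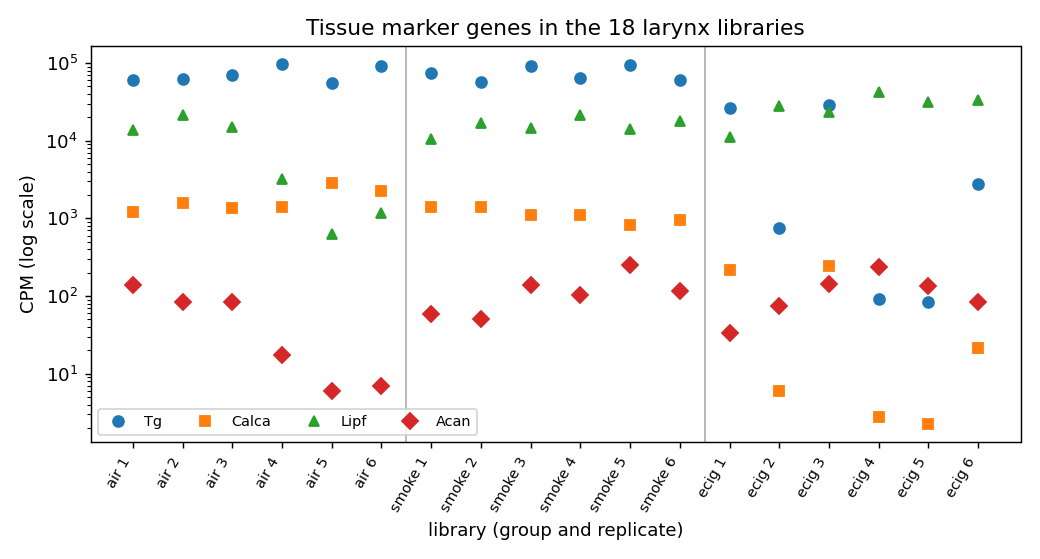
CPM (log scale) of the thyroid genes Tg and Calca, the lipase gene Lipf and the cartilage gene Acan in each of the 18 libraries; each point is 1 library. Calca reaches at most 244 CPM in the 6 e-cigarette libraries and at least 827 CPM in the others, and Acan reaches at most 17.6 CPM in air 4, 5 and 6.

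After cigarette smoke, Cyp1a1 and Ahrr of the aryl hydrocarbon receptor (AhR) response, the secreted-protein genes Bpifb9a and Cst10 and the fatty acid synthase gene Fasn were higher than in air, and chaperone genes such as Dnaja1 were lower. Cyp1a1 (ENSMUSG00000032315, chromosome 9, 57687928 to 57703824), a cytochrome P450 induced through AhR, rose 4.50-fold, from 0.668 ± 0.336 CPM in air to 3.02 ± 0.703 CPM in smoke (log2 fold change 2.17, SE 0.27, adjusted p = 0.00119, higher in 6 of 6 samples). Ahrr (ENSMUSG00000021575, chromosome 13, 74211118 to 74292331), the AhR repressor, rose from 0.289 ± 0.112 to 1.14 ± 0.390 CPM (1.96, SE 0.33, adjusted p = 0.00657). Bpifb9a (ENSMUSG00000067998, chromosome 2, 154257854 to 154271245), of a family of secreted lipid-binding proteins, rose from 3.59 ± 4.51 to 103 ± 49.0 CPM (4.86, SE 0.67, adjusted p = 0.00565). Cst10 (ENSMUSG00000033156, chromosome 2, 149405057 to 149410293), a cystatin, rose from 0.145 ± 0.248 to 7.70 ± 5.46 CPM (5.64, SE 0.79, adjusted p = 0.00533). Dnaja1 (ENSMUSG00000028410, chromosome 4, 40722150 to 40737149), a co-chaperone, fell from 293 ± 104 CPM in air to 117 ± 9.26 CPM in smoke (-1.32, SE 0.17, adjusted p = 0.00119).

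In all, 279 genes were called in smoke versus air, 171 higher and 108 lower (1.59% of those tested; 36 and 18 by at least 2-fold). In 426 of the tested genes (2.43%, against 0.216% by chance) the groups did not overlap. The other large increases were those of Pip (3.17, SE 0.63), Smgc (2.22, SE 0.46), Fasn (2.03, SE 0.41), the tight junction gene Cldn11 (1.86, SE 0.34), the adenylyl cyclase Adcy8 (1.71, SE 0.39) and Scd1 (1.58, SE 0.27). The other large decreases were those of the growth factor Areg (-3.19, SE 0.73), the phosphatase Dusp2 (-2.80, SE 0.62), Hspa1a and Hspa1b (-2.10 each, SE 0.34 and 0.41), Fos (-2.06, SE 0.43), Atf3 (-1.84, SE 0.40), the chemokine Ccl20 (-1.69, SE 0.40), the surfactant gene Sftpa1 (-1.60, SE 0.30) and the prostaglandin synthase Ptgs2 (-1.45, SE 0.35). The adjusted p-values of these genes lay between 0.00737 and 0.0429. Without air 3 Areg was at -1.55, Dusp2 at -1.96 and Atf3 at -1.24, while Bpifb9a was at 5.83, and without air 2 Cst10 was at 7.14. Of the 37 called genes named for this comparison, Cst10, Bpifb9a, Cyp1a1, Ahrr, Cldn11, Scd1, Hspa1a, Sftpa1, Dnaja1, Thrsp, Hsp90aa1 and Hsph1 were called in each of 18 fits without 1 library. The other 25 lost the call in at least 1 fit (highest adjusted p 0.113). The losses numbered 23 without smoke 5, 22 without air 5, 21 without smoke 6, 17 without smoke 4, 16 without smoke 3 and 13 without air 6. They numbered 11 without air 4 or smoke 1, 8 without smoke 2, and 1 to 5 without air 2, air 3, ecig 1, ecig 2, ecig 3 or ecig 4. The number of called genes fell to 50 without air 5, 58 without smoke 5, 70 without smoke 6, 84 without smoke 4 and 96 without air 6. It was 108 without smoke 3, 120 without air 4, 177 without smoke 1 and 184 without smoke 2, and was 562 without air 2.

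**Figure D2:**
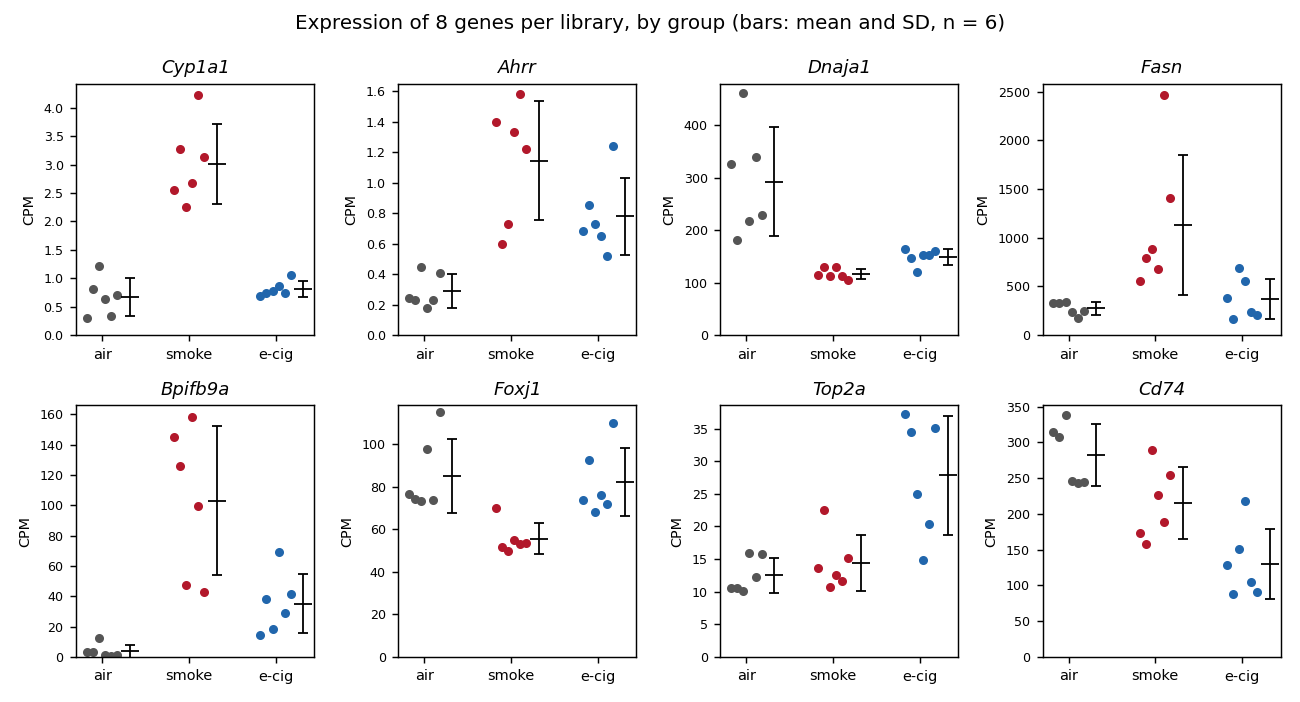
CPM of 8 genes in air, smoke and e-cigarette libraries; points are libraries, and bars give the mean and SD of 6. Cyp1a1 was at 2.25 CPM or more in each smoke library and at 1.22 CPM or less in each air library, and Dnaja1 averaged 293 CPM in air and 117 CPM in smoke.

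Of 11 tested AhR targets 2 rose, Cyp1a1 and Ahrr, and 4 rose when adjusted over the list alone (median 0.57, camera adjusted p = 0.00233, adjusted p = 0.313 with an estimated correlation). With 4 composition covariates Cyp1a1 was at 2.12 with a larger SE (0.44, against 0.27 without them). It was no longer called (adjusted p = 0.0772, range 1.87e-10 to 0.141 over 34 alternatives). The list was then at 0.38 (camera adjusted p = 0.149, range 3.45e-04 to 0.313 over 27 alternatives). Among the other members, Cyp1b1 was at 0.69 (adjusted p = 0.0719) and Tiparp at -0.30 (adjusted p = 0.267). Of 38 xenobiotic metabolism genes 1 rose, as did 1 adjusted over the list alone, with 19 above and 19 below 0 (median 0.01, camera adjusted p = 0.799). Of 38 genes of the NRF2 and oxidative stress response 1 rose, the pentose phosphate enzyme Tkt (0.61, adjusted p = 0.0428), as did 1 adjusted over the list alone. Their median was 0.00, the mean 0.01 and the direction of the test down (camera adjusted p = 0.892). Nqo1, Gclc, Hmox1, Il1b, Muc5ac, Muc5b, Krt5, Krt13 and Scgb1a1 did not pass either (log2 fold changes -0.46 to 1.18, adjusted p 0.0724 to 0.996). Among 30 inflammatory cytokine and chemokine genes 3 fell, Cxcl16 (-0.57), Ccl20 and Ptgs2, and 6 adjusted over the list alone (median -0.29, camera adjusted p = 0.00391, adjusted p = 0.313 with an estimated correlation). Without air 1, 2 and 3 this list's median was -0.28 and its camera adjusted p 0.289. The latter ranged from 0.00105 to 0.313 over 27 alternatives.

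Of 19 heat shock genes 9 fell and 10 were not called, with 14 called when adjusted over the list alone (median -0.49, camera adjusted p = 3.66e-15, adjusted p = 0.313 with an estimated correlation). The chaperone gene Hsp90aa1 fell from 700 ± 217 to 329 ± 31.2 CPM (-1.09, SE 0.17, adjusted p = 0.00565) and Hsph1 fell by 1.22 (SE 0.19, adjusted p = 0.00569). Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) averaged 79.1 ± 45.4 CPM in air and 18.4 ± 3.20 CPM in smoke. Its reads can be shared with the near-identical Hspa1b. Of 25 immediate early genes 3 fell, Fos, Atf3 and Jun (-0.57), and 20 adjusted over the list alone (median -0.87, camera adjusted p = 1.23e-12, adjusted p = 0.313 with an estimated correlation). Of 25 genes of the unfolded protein and integrated stress response 3 fell, Ddit3 (-0.61), Dnajb9 (-0.77) and Atf3, and 7 adjusted over the list alone (median -0.26, camera adjusted p = 4.53e-06, adjusted p = 0.314 with an estimated correlation). Without air 1, 2 and 3 the median of this list was -0.19 and its camera adjusted p 0.0573, within a range of 4.84e-09 to 0.314 over 27 alternatives.

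Of 28 lipogenesis and sterol synthesis genes 6 rose and 22 were not called, with 9 higher when adjusted over the list alone (median 0.14, camera adjusted p = 0.00138, adjusted p = 0.388 with an estimated correlation). Fasn (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547), the fatty acid synthase, was at 276 ± 68.3 CPM in air and 1130 ± 718 CPM in smoke, and the desaturase Scd1 at 912 ± 134 and 2722 ± 1355 CPM. The carboxylase Acaca rose by 1.39 (SE 0.27) and the citrate lyase Acly by 1.00 (SE 0.20). Among 18 adipocyte genes 1 rose, the lipogenic regulator Thrsp (1.04, SE 0.17, adjusted p = 0.00657), and 5 adjusted over the list alone (median 0.32, camera adjusted p = 2.71e-05, adjusted p = 0.313 with an estimated correlation). With the 4 composition scores as covariates, of which it is 1, the adipocyte median was -0.10 (camera adjusted p = 0.389, range 1.91e-06 to 0.528 over 27 alternatives). Adipoq ranged from 74.9 to 104 CPM in air and 81.7 to 111 CPM in smoke. Of 28 fatty acid oxidation and PPAR target genes none was called by edgeR over all genes and 12 adjusted over the list alone (median 0.26, camera adjusted p = 2.08e-06, adjusted p = 0.313 with an estimated correlation). With the same covariates the median of this list was 0.05 (camera adjusted p = 0.985, range 5.09e-08 to 0.985 over 27 alternatives), Fasn was at 0.52 (SE 0.37, adjusted p = 0.603) and Scd1 at 0.78 (SE 0.31, adjusted p = 0.308). Over 34 alternatives the adjusted p ranged from 6.35e-04 to 0.708 for Fasn and from 1.52e-06 to 0.308 for Scd1.

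Of 33 ciliated cell genes 3 fell and 21 fell when adjusted over the list alone (median -0.53, camera adjusted p = 4.31e-13, adjusted p = 0.313 with an estimated correlation). Foxj1 (ENSMUSG00000034227, chromosome 11, 116330704 to 116335399), the transcription factor of multiciliated cells, fell from 85.0 ± 17.3 to 55.5 ± 7.25 CPM (-0.61, SE 0.13, adjusted p = 0.0281), and the axonemal genes Cfap52 (-0.54) and Spag6l (-0.59) fell with it. The airway secretory gene Bpifa1 fell from 15724 ± 2335 to 9452 ± 1331 CPM (-0.73, adjusted p = 0.0239) and the collectin Sftpd by 0.84 (adjusted p = 0.0345). Among 18 glandular acinar genes 1 rose, Pip, and 7 adjusted over the list alone (median 0.75, camera adjusted p = 6.41e-08, adjusted p = 0.313 with an estimated correlation). The glandular median lay between 0.14, with 5 covariates (camera adjusted p = 0.804, range 5.72e-15 to 0.804 over 27 alternatives), and 2.39, and it was 0.33 and still called without air 4, 5 and 6. Of 37 fibrillar matrix genes 2 rose, the fibrillin Fbn1 (0.86, SE 0.18) and the collagen Col5a3 (0.72), against 15 higher and 1 lower adjusted over the list alone (median 0.58, camera adjusted p = 2.00e-07, adjusted p = 0.397 with an estimated correlation). None of 20 cartilage genes was called by edgeR, over all genes or adjusted over the list alone, and their median was 1.02 (camera adjusted p = 2.70e-08; adjusted p = 0.331 with an estimated correlation). Acan was at 50.2 to 255 CPM in smoke beside the low values of air 4, 5 and 6. Without air 4, 5 and 6 the ciliated median was -0.16 (camera adjusted p = 0.0809) and the cartilage median 0.32 (0.112). With 4 composition covariates Foxj1 was at -0.28 (SE 0.17, adjusted p = 0.534, range 0.00125 to 0.534 over 34 alternatives), the ciliated median was -0.01 and the fibrillar matrix median turned to -0.21 (camera adjusted p = 1.71e-05). Over 27 alternatives the adjusted p of these lists reached 0.647, 0.753 and 0.397, from 1.13e-19, 1.31e-14 and 7.51e-10.

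E-cigarette aerosol exposure went with lower transcripts of thyroid and parathyroid tissue, of antigen presentation and of the unfolded protein response, and with higher transcripts of mucins, glands, skeletal muscle and the cell cycle. The iodide transporter gene Slc5a5 of thyroid follicles fell from 43.5 ± 7.36 CPM in air to 4.71 ± 5.74 CPM (log2 fold change -3.20, adjusted p = 8.32e-04), and Calca fell by 4.42 (SE 1.02, adjusted p = 0.00505). Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812646), the MHC class II invariant chain, fell from 283 ± 42.9 to 130 ± 49.0 CPM (-1.12, SE 0.20, adjusted p = 4.77e-04). The membrane mucin Muc16 rose from 193 ± 43.8 to 473 ± 99.6 CPM (1.29, SE 0.17, adjusted p = 2.53e-05), and the topoisomerase Top2a (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189) of dividing cells from 12.5 ± 2.68 to 27.8 ± 9.13 CPM (1.15, SE 0.22, adjusted p = 7.56e-04). Ahrr rose from 0.289 ± 0.112 to 0.779 ± 0.252 CPM (1.43, SE 0.33, adjusted p = 0.00367), and Cyp1a1 was at 0.812 ± 0.135 CPM (0.29, SE 0.29, adjusted p = 0.493). Ahrr was at 1.25 without ecig 2, 4, 5 and 6 (adjusted p = 0.137) and at 1.70 (SE 0.60) with the thyroid score as covariate (adjusted p = 0.390, range 0.00263 to 0.390 over 32 alternatives).

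In all, 4406 genes were called in e-cigarette versus air, 2128 higher and 2278 lower (25.1% of those tested; 385 and 692 by at least 2-fold), and the groups did not overlap in 1843 tested genes (10.5%, against 0.216% by chance). The largest increases were those of Pip (3.84, SE 0.64), Bpifb9a (3.31, SE 0.64), Cst10 (3.19, SE 0.85), Smr2 (2.50, SE 0.87), Smgc (2.35, SE 0.46), Csn3 (2.27, SE 0.79), the lactoperoxidase gene Lpo (2.12, SE 0.63), Gstm3 (2.07, SE 0.64), Mup6 (2.05, SE 0.51) and Clec3a (2.04, SE 0.54). In Lpo, Smr2 and Csn3 the e-cigarette values overlapped those of air 1, 2 and 3, and air 4, 5 and 6 were lower. Lpo was at 21.6, 16.7 and 22.6 CPM in air 1, 2 and 3 and at 11.2, 0.569 and 1.40 CPM in air 4, 5 and 6. It was at 16.5 to 102 CPM in e-cigarette. Without air 4, 5 and 6, 7 of the 56 called genes named for this comparison lost the call. Smr2, Gstm3 and Mup6 belong to families of near-identical copies. The ammonium transporter Rhcg (ENSMUSG00000030549, chromosome 7, 79593363 to 79617657) had 0 counts over the e-cigarette group against 2725 in air, at least 994-fold lower (adjusted p = 0.0184). Gcm2 (ENSMUSG00000021362, chromosome 13, 41101427 to 41111035), the parathyroid transcription factor, had 3 counts against 1785, a ratio of 651 (counting interval 222 to 3159, adjusted p = 0.00259). Pth (ENSMUSG00000059077, chromosome 7, 113385580 to 113388570), parathyroid hormone, fell from 1868 ± 1523 to 2.34 ± 2.41 CPM (-9.62, SE 2.27, adjusted p = 0.00575). These 3 genes were near 0 in some libraries of the other groups too: Pth was at 2.34 CPM in air 4 and at 0.128, 0.0563 and 5.68 CPM in smoke 1, 3 and 6, and Rhcg at 0 in these 4. With voom Pth was at -7.59 (adjusted p = 0.409, range 1.17e-07 to 0.959 over 34 alternatives), and none of the 3 was called with voom or without ecig 2, 4, 5 and 6. Chga (-7.72, SE 1.53), Spink8 (-6.94, SE 1.24), Kl (-6.44, SE 1.36), Sycp2l (-6.30, SE 1.55), Cdh20 (-4.81, SE 1.01), Mcoln3 (-4.77, SE 1.14) and Cryba2 (-4.63, SE 0.95) fell as well. Like Pth, each of them was lowest in air 4 among the air libraries, such as Kl at 0.760 CPM and Cdh20 at 0. Each was also lower in smoke 1, 3 and 6 than in smoke 2, 4 and 5. None of them was called by edgeR without ecig 2, 4, 5 and 6 (adjusted p 0.122 to 0.297). Of 56 called genes named for this comparison 4 lost the call in some fit without 1 library. They were Smr2 (adjusted p = 0.135 without ecig 6, and lost without any single library but air 2, smoke 6 and ecig 1), Csn3 (0.113 without ecig 6, and lost without air 1, 4, 5 or 6, smoke 1, 2, 3, 5 or 6, or ecig 4 or 5), Gstm3 (0.0554 without air 3, and lost without air 1, air 2 or ecig 5) and Lpo (0.0519 without ecig 6). Without ecig 6 Smr2 was at 1.73, without air 2 Smr2 was at 3.37 and Cst10 at 4.69, without air 3 Bpifb9a was at 4.28, without ecig 1 Gcm2 was at -9.97 (-9.03 with it), Sycp2l at -7.00 and Slc5a5 at -4.01, and without ecig 3 Calca was at -5.14. Without ecig 2, 4, 5 and 6, in which Tg took under 1% of counts, 688 genes were called and 675 of the 4406 kept call and direction. Of the 56 named calls 32 were lost in that fit, which keeps only ecig 1 and 3 and so can call fewer genes. Some of the lost genes had no smaller fold there, such as Cdh20 (-7.41) and Gstm3 (2.44), while others shrank, such as Smr2 (1.37) and Csn3 (0.58). With the thyroid score as covariate 50 were lost and 6 changed sign.

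Of 16 thyroid and parathyroid genes 12 fell and 1 rose, with 13 lower and 1 higher adjusted over the list alone (median -2.98, camera adjusted p = 3.25e-07, adjusted p = 0.369 with an estimated correlation). The thyrotropin receptor Tshr (-2.37, adjusted p = 2.37e-04) and the transcription factor Foxe1 (-2.57, adjusted p = 0.00118) were among them. Tg did not pass (-2.88, SE 1.08, adjusted p = 0.0636), although each e-cigarette library lay below each air library. Its adjusted p ranged from 2.96e-06, with DESeq2, to 0.896 over 34 alternatives. Without ecig 2, 4, 5 and 6 Tg was at -1.41 and its adjusted p was 0.00701. Without ecig 1 the list median was -3.57 and Tg was called (-3.49, adjusted p = 0.0455), and without ecig 3 Tg was called as well (-3.60, adjusted p = 0.0368).

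Of 26 secretory and mucin genes 11 rose, among them Muc16, Muc20 (0.96, adjusted p = 0.00155) and Muc5ac (1.22, SE 0.28, adjusted p = 0.00340), and 14 adjusted over the list alone (median 0.78, camera adjusted p = 2.54e-04, adjusted p = 0.408 with an estimated correlation). Of 18 glandular acinar genes 10 rose, and 12 adjusted over the list alone (median 1.34, camera adjusted p = 9.92e-07, adjusted p = 0.369 with an estimated correlation). The glandular median lay between 0.01, with 5 covariates, and 3.03, without air 1, 2 and 3, and it was 0.78 and still called without air 4, 5 and 6. Beside these genes, Lipf was at 11023 to 42502 CPM in the e-cigarette libraries, and of 20 cartilage genes 7 rose and 1 fell, with 11 higher and 1 lower adjusted over the list alone (median 1.12, camera adjusted p = 2.55e-04, adjusted p = 0.580 with an estimated correlation). The cartilage median was 0.49 without air 4, 5 and 6 (camera adjusted p = 0.415) and 0.32 with the thyroid score as covariate (0.327), in a range of 4.55e-10 to 0.904 over 27 alternatives. Of 20 fast skeletal muscle genes 15 rose, such as Casq1 (0.73) and Ckm (0.61), and 17 adjusted over the list alone (median 0.53, camera adjusted p = 3.25e-07, adjusted p = 0.369 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose in 15 of 43 cases, for example Ndufs1 (0.58, SE 0.08), and in 19 adjusted over the list alone (median 0.26, camera adjusted p = 7.66e-06, adjusted p = 0.580 with an estimated correlation). With 5 covariates the median of this list was 0.16 (camera adjusted p = 0.0751, range 2.57e-08 to 0.580 over 27 alternatives). Of 13 mitochondrial genome genes 9 rose, such as mt-Nd2 (0.53), and 9 adjusted over the list alone (median 0.47, camera adjusted p = 2.54e-04, adjusted p = 0.369 with an estimated correlation). Muc16 was at 0.82 (SE 0.29, adjusted p = 0.198, range 8.02e-11 to 0.388 over 34 alternatives) with 4 composition covariates. With them the medians of the secretory and mitochondrial genome lists were 0.20 and 0.19 and their camera adjusted p 0.195 and 0.154, within ranges of 2.70e-07 to 0.638 and 3.65e-06 to 0.369 over 27 alternatives.

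Of 34 cell cycle genes 23 rose, such as Top2a, Nusap1 (1.12) and Prc1 (0.77), and 25 adjusted over the list alone (median 0.82, camera adjusted p = 9.92e-07, adjusted p = 0.369 with an estimated correlation). Of 16 antigen presentation genes 13 fell, such as Cd74, H2-Ab1 (-0.88) and H2-Eb1 (-0.76), and 14 adjusted over the list alone (median -0.52, camera adjusted p = 3.25e-07, adjusted p = 0.369 with an estimated correlation). Both lists were called in 26 of 27 alternatives, all but the estimated correlation. Top2a was at 1.93 (SE 0.32, adjusted p = 0.0139) and Cd74 at -1.56 (SE 0.29, adjusted p = 0.0232) with 4 composition covariates. With the thyroid score as covariate Top2a was at 1.81 (SE 0.36) and Cd74 at -1.38 (SE 0.38), both with a larger fold change and SE than without it. Neither was called in that fit, which called 1 gene in all (adjusted p = 0.145 and 0.239). These are the highest adjusted p of 34 alternatives, and the lowest are 7.23e-06 and 9.10e-07.

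Of 25 genes of the unfolded protein and integrated stress response 14 fell and 1 rose, with 15 lower and 2 higher adjusted over the list alone (median -0.46, camera adjusted p = 3.24e-06, adjusted p = 0.369 with an estimated correlation). The endoplasmic reticulum genes Sdf2l1 (-1.67, adjusted p = 1.88e-05) and Creld2 (-1.51, adjusted p = 2.47e-05) fell most clearly. Neither was called with the thyroid score as covariate, in the fit that called 1 gene in all. Without ecig 2, 4, 5 and 6 both were still called (-1.29 and -1.32). Within the e-cigarette group Sdf2l1 was lowest in ecig 4 and 5 (12.3 and 14.5 CPM), which had the least Tg, and higher in ecig 1 and 3 (27.8 and 29.1 CPM). These falls were thus not separated from the thyroid share. Of 25 immediate early genes 12 fell, Jun by 1.03, and 18 adjusted over the list alone (median -0.94, camera adjusted p = 5.15e-05, adjusted p = 0.494 with an estimated correlation). Of 19 heat shock genes 7 fell, such as Dnaja1 (-0.97) and Hspa1a (-1.81), and 1 rose, with 9 lower and 1 higher adjusted over the list alone (median -0.29, camera adjusted p = 0.0175, adjusted p = 0.588 with an estimated correlation). The heat shock median was -0.17 without air 1 (camera adjusted p = 0.101) and -0.26 without air 3 (0.0714), and the immediate early median was -0.19 without air 1, 2 and 3 (0.318). Over 27 alternatives the adjusted p of these lists ranged from 1.27e-05 to 0.588 and from 7.07e-10 to 0.494. Of 33 ciliated cell genes 3 rose, and none adjusted over the list alone by edgeR (median 0.19, camera adjusted p = 0.0483, adjusted p = 0.776 with an estimated correlation). The ciliated median was 0.10 without air 1 (camera adjusted p = 0.268), 0.13 without air 2 (0.139), 0.11 without air 3 (0.199), 0.17 without ecig 2 (0.0714), 0.16 without ecig 4 (0.0874) and 0.11 without ecig 6 (0.226). It was -0.09 without ecig 2, 4, 5 and 6 (0.797) and -0.15 without air 1, 2 and 3 (0.174), in a range of 4.88e-08 to 0.803 over 27 alternatives. Of 11 AhR targets 3 rose and 1 fell, as many as adjusted over the list alone (median 0.41, camera adjusted p = 0.112, fry adjusted p = 0.0218). This list stayed uncalled in the same direction in 24 of 27 alternatives, and fry was among the others. Of 38 NRF2 genes 5 rose and 5 fell, as many as adjusted over the list alone (median 0.02, camera adjusted p = 0.799). Cyp1b1, Tiparp, Nqo1, Gclc, Hmox1, Il1b, Muc5b, Krt5, Krt13, Foxj1 and Scgb1a1 did not pass (-0.71 to 1.21, adjusted p 0.0924 to 0.889).

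Set against each other, Cyp1a1 was higher in the smoke libraries and transcripts of motile cilia were higher in the e-cigarette libraries. Against air, the ciliated median was -0.53 in smoke and 0.19 in e-cigarette. Cyp1a1 was 1.88 higher on the log2 scale in smoke than in e-cigarette (SE 0.26, adjusted p = 1.07e-04), in 6 of 6 samples. With 4 composition covariates it was at 1.93 with a larger SE of 0.54 and was no longer called (adjusted p = 0.783, range 7.82e-10 to 0.792 over 34 alternatives). Of 33 ciliated cell genes 26 were lower in smoke and 7 were not called, with 30 lower adjusted over the list alone (median -0.70, camera adjusted p = 4.52e-14, adjusted p = 0.516 with an estimated correlation). Spag6l (ENSMUSG00000022783, chromosome 16, 16753016 to 16829456), of the ciliary central apparatus, was at 9.26 ± 0.664 CPM in smoke and 18.3 ± 4.04 CPM in e-cigarette (-0.99, SE 0.15, adjusted p = 1.76e-04), and Foxj1 was lower in smoke (-0.56, SE 0.13, adjusted p = 0.00660), as were Lrrc23 (-0.83) and Ccdc40 (-0.74). Without ecig 2, 4, 5 and 6 the ciliated median was -0.48 (camera adjusted p = 2.73e-08), and Foxj1 (-0.36) and Spag6l (-0.69) no longer passed (adjusted p = 0.420 and 0.112). Over 34 alternatives their adjusted p ranged from 9.86e-04 to 0.948 and from 1.17e-08 to 0.849.

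In all, 2897 genes were called between smoke and e-cigarette, 1828 higher and 1069 lower in smoke (16.5% of those tested; 533 and 76 by at least 2-fold), and the groups did not overlap in 1644 tested genes (9.37%, against 0.216% by chance). The largest differences toward smoke included Pth, Gcm2 and Calca of the Thyroid list. Pth (8.11, SE 2.15, adjusted p = 0.0173) was at 654 ± 851 CPM against 2.34 ± 2.41 CPM and above the e-cigarette mean in 4 of 6 smoke samples. Next came Gcm2 with 745 counts against 3 (ratio 262, counting interval 89.3 to 1274, adjusted p = 0.0149), Chga (6.04, SE 1.42), Spink8 (5.42), Kl (5.34), Sycp2l (5.12), Pnoc (4.16, SE 0.51), Tubb1 (3.96), Serpina3j (3.81) and Calca (3.77, SE 0.99). Chga, Spink8, Kl and Sycp2l were, like Pth and Gcm2, high only in smoke 2, 4 and 5 of the smoke libraries. Chga was at 1407, 814 and 718 CPM there and at 16.8, 16.0 and 14.9 CPM in smoke 1, 3 and 6. Higher in e-cigarette were Cdc20b (-1.77), Ccna1 (-1.68), Ccl20 (-1.55), the neutrophil and epithelial surface gene Cd177 (-1.45, at 16.7 ± 2.59 against 45.5 ± 15.3 CPM), Atp12a (-1.39), S100g (-1.37), Skint3 (-1.37), Itln1 (-1.33), Calcoco2 (-1.28) and Pklr (-1.24). Of 40 called genes named for this comparison 6 lost the call in some fit without 1 library. They were Sycp2l (highest adjusted p 0.0767, without smoke 2, and lost without smoke 4 or 5 or any ecig library), S100g (0.0732 without ecig 6, also smoke 3, 4 and 5 and ecig 2) and Skint3 (0.0721 without ecig 5, also smoke 2 and 3 and ecig 1 and 3). The others were Calcoco2 (0.0652 without ecig 2, also smoke 2, 3 and 5 and ecig 4 and 6), Pklr (0.0573 without smoke 1, also smoke 4 and ecig 6) and Atp12a (0.0545 without smoke 3, also ecig 2). Without ecig 3 Serpina3j was at 5.41, Tubb1 at 4.66 and Calca at 4.49, and without smoke 2 Pth was at 7.24, Gcm2 at 6.92 (7.64 with it), Chga at 5.38 and Sycp2l at 4.44. Without ecig 1 Gcm2 was at 8.57 and Sycp2l at 5.81, and without smoke 6 Atp12a was at -2.03. Without ecig 2, 4, 5 and 6, 147 genes were called, 145 of them among the 2897 in the same direction. Of the 40 named calls 33 were lost in that fit, which keeps only ecig 1 and 3 and so can call fewer genes. With the thyroid score or with 4 composition covariates 36 were lost and 4 changed sign.

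Of 16 thyroid and parathyroid genes 12 were higher in smoke, such as Slc5a5 (3.35) and Tshr (2.43), with 13 higher and 1 lower adjusted over the list alone (median 2.71, camera adjusted p = 5.52e-07, adjusted p = 0.516 with an estimated correlation). Without ecig 1 the list median was 3.31 and Slc5a5 was at 4.15. Of 16 antigen presentation genes 9 were higher in smoke, such as H2-K1 (0.56) and Tap2 (0.68), and 13 adjusted over the list alone (median 0.49, camera adjusted p = 5.52e-07, adjusted p = 0.516 with an estimated correlation). Of 18 adipocyte genes 8 were higher, such as Plin1 (1.04) and Fabp4 (0.64), and 11 adjusted over the list alone (median 0.56, camera adjusted p = 3.01e-05, adjusted p = 0.516 with an estimated correlation), and the lipogenic Scd1 was 1.29 higher (SE 0.26). The adipocyte median was 0.26 without ecig 2, 4, 5 and 6, where Plin1 (0.58, adjusted p = 0.318, range 2.10e-05 to 0.962) and Fabp4 (0.36, adjusted p = 0.461, range 4.07e-04 to 0.938) were no longer called. With 4 covariates, 1 of which is this list, the median was 0.14 (camera adjusted p = 0.778, range 1.58e-06 to 0.778). Of 17 endothelial genes 5 were higher, such as Emcn (0.96) and Plvap (1.78), and 6 adjusted over the list alone (median 0.32, camera adjusted p = 5.93e-04, adjusted p = 0.516 with an estimated correlation). Lower in smoke were 6 of 34 cell cycle genes, such as Top2a (-0.96) and Prc1 (-0.74), and 13 adjusted over the list alone (median -0.50, camera adjusted p = 3.16e-06, adjusted p = 0.516 with an estimated correlation). Also lower were 6 of 26 secretory genes, such as Muc16 (-0.65) and Agr2 (-0.89), and 8 adjusted over the list alone (median -0.43, camera adjusted p = 0.00108, adjusted p = 0.516 with an estimated correlation). Of 19 heat shock genes 5 were lower, such as Hsph1 (-0.72) and Hsp90aa1 (-0.60), and 10 adjusted over the list alone (median -0.33, camera adjusted p = 1.79e-04, adjusted p = 0.516 with an estimated correlation). Fast skeletal muscle (8 of 20 lower, 9 adjusted over the list alone, median -0.36, camera adjusted p = 3.01e-05) and mitochondrial genome genes (8 of 13 lower, 8 adjusted over the list alone, median -0.40, camera adjusted p = 3.04e-05) were lower too, both with an adjusted p = 0.516 with an estimated correlation. With the thyroid score as covariate their medians were -0.01 (camera adjusted p = 0.201) and -0.15 (0.0676), in ranges of 4.01e-07 to 0.927 and 2.70e-07 to 0.516 over 27 alternatives. Of 11 AhR targets 2 were higher, as many as adjusted over the list alone. The list median was -0.14, the mean 0.32 and the direction of the test up (camera adjusted p = 0.562). Ahrr (0.54), Cyp1b1, Tiparp, Nqo1, Gclc, Hmox1, Il1b, Muc5ac, Muc5b, Krt5, Krt13 and Scgb1a1 did not pass (-0.88 to 0.54, adjusted p 0.115 to 0.981). For the secretory list, leaving out ecig 2, 4, 5 and 6 gave a median of -0.11 (camera adjusted p = 0.184, range 3.15e-05 to 0.728 over 27 alternatives).

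**Figure D3:**
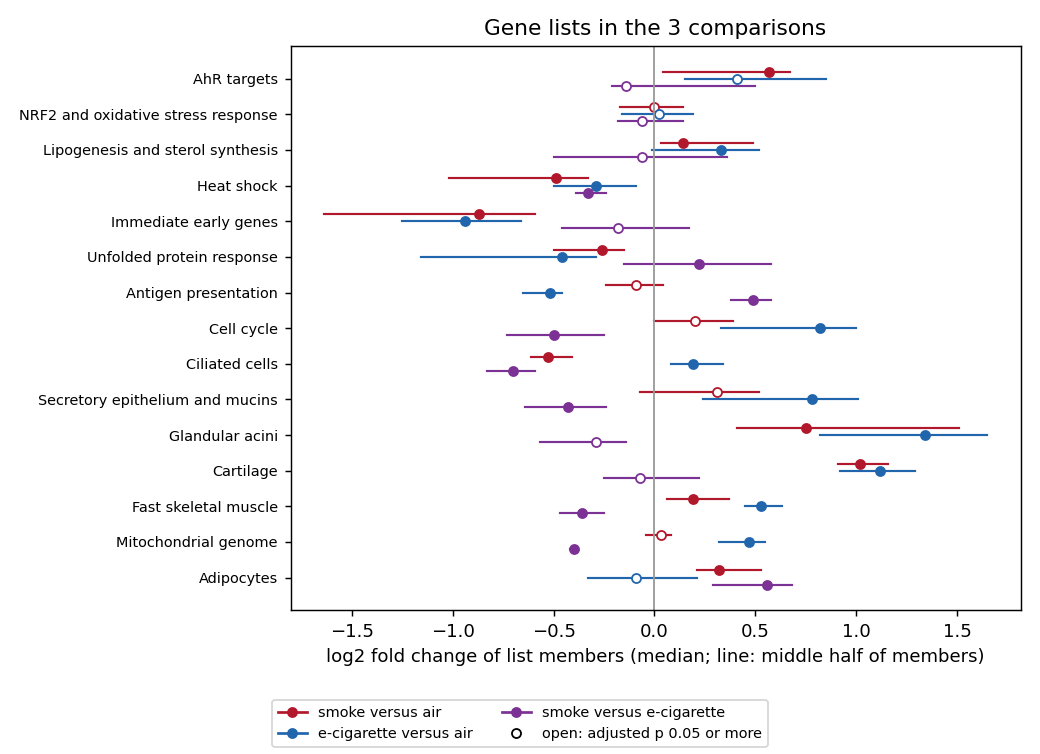
Median log2 fold change of 15 gene lists in the 3 comparisons; lines span the middle 50% of each list's genes, and filled points have a camera adjusted p below 0.05 with the preset correlation. The ciliated cell list lies at -0.53 in smoke versus air, 0.19 in e-cigarette versus air and -0.70 in smoke versus e-cigarette.

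The 2 exposures shared calls against air. Called in both comparisons and in the same direction were 182 genes, 129 higher and 53 lower, against 20.7 and 14.0 for independent lists of these sizes, and 3 were called in opposite directions. Pip, Bpifb9a, Cst10, Smgc, Ahrr, Dnaja1, Hspa1a and Jun were among the shared calls. The log2 fold changes of the 17537 genes correlated with r = 0.56 across genes, which are not independent replicates, and with a covariance of 0.124. Both comparisons use the same air libraries. In simulations, all 18 libraries, air included, were drawn without change around the air means. These simulated comparisons, sharing a simulated air group, gave r = 0.50 and a covariance of 0.0307, which the observed covariance exceeded by 0.0936. They gave 0 shared calls by edgeR, but with no effect simulated few calls can arise, so this is no baseline for the 182. Genes were drawn independently, so differences that many genes share within the air group were not simulated. With the air libraries split 3 and 3, the medians over 20 assignments were r = 0.34, a covariance of 0.0912 and 29 shared calls, with ranges of 0.09 to 0.49, 0.0325 to 0.111 and 0 to 396. The lowest covariance and the highest overlap both came from the assignment that set air 4, 5 and 6 against smoke. Without 1 library the shared calls numbered 356 (air 2), 91 (air 4), 35 (air 5), 76 (air 6), 79 (smoke 3), 59 (smoke 4), 46 (smoke 5) and 51 (smoke 6).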

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

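The test for a library far from the others of its group was planned. It was also applied to Tg and Calca, singled out after their values were seen, Calca for e-cigarette versus air. It compared the gap between the extreme library and its nearest neighbour with the range of the 6 libraries. Of 363 groups of 6 values, 32 passed the 95% limit. Independent values with a normal distribution would pass in about 1 in 20, or 18.2. The CPM values were not log-transformed, and most genes were named because they were called in these same libraries. Nor are the genes independent, so 18.2 is no chance level here.

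Air 3 accounted for 9 of the 32, against 1 to 3 in the other libraries with any. It had the highest CPM of its group for Areg (27.1), Atf3 (58.1), Bpifb9a (12.6), Dusp2 (344), Lamb3 (154), Mt2 (6.54), Ptgs2 (13.8) and Sesn2 (36.6), and the lowest for Foxe1 (49.4). Air 2 was highest for Cst10 (0.633), Fos (104) and Jun (189). Air 5 was highest for Calcoco2 (1.42) and mt-Nd2 (4332) and in the number of genes detected (26788, against 23735 to 24662 in the other air libraries).

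Among the smoke libraries, smoke 1 was highest for Cdc20b (1.21) and Foxj1 (69.9), smoke 2 for Fos (17.0) and Top2a (22.5), smoke 3 for Creld2 (106) and Tshr (43.8) and lowest for Hspa1a (12.0). Smoke 4 was highest for Csn3 (12.9), smoke 5 for Acaca (361), Acly (558) and Clec3a (9.84), and smoke 6 for Atp12a (1.56). Among the e-cigarette libraries, ecig 1 was highest for Cd79b (1.31), ecig 3 for Serpina3j (0.671) and lowest for Hsp90aa1 (413), and ecig 6 was highest for Smr2 (176) and lowest for Gstm3 (1.10). No explanation was tested for these values here.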

How the results depend on the processing

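The settings that leave out sets of libraries, use the thyroid score alone or use 5 covariates, and the fits of the overlap without 1 library, were chosen after the results were seen. The others were planned. The e-cigarette group differs from the others in its thyroid score, so that with it as a covariate group and score can hardly be separated, and the median SE of the named genes rose from 0.29 to 0.54 in e-cigarette versus air and from 0.29 to 0.49 in smoke versus e-cigarette. Changes of 1.5-fold were mostly not recovered in the simulated data, so that changes of that size can be missed in these libraries.

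For smoke versus air (279 genes), DESeq2 called 999, 275 of them among the 279 in the same direction, voom 1120, surrogate variables 1530, no filter 184, only the 2 groups 109, a threshold of 0.01 25 and a log2 fold change of at least 1 54. With 4 composition covariates 6 genes were called, with 5 covariates 9 and with the thyroid score 115. Without ecig 2, 4, 5 and 6 the number was 163, without air 4, 5 and 6 451, and without air 1, 2 and 3 2198. Leaving out 1 library gave 50 (air 5) to 562 (air 2). For e-cigarette versus air (4406 genes), the counts were 115 with 4 covariates, 1 with the thyroid score, 200 with 5 covariates, 688 without ecig 2, 4, 5 and 6, 2466 at 0.01 and 1077 at a log2 fold change of at least 1. Of the 4406 genes, 326 changed sign with 4 covariates. For smoke versus e-cigarette (2897 genes), edgeR called 0 with 4 covariates, the thyroid score or 5 covariates (1015, 1431 and 1012 at an unadjusted p below 0.05; DESeq2 without covariates called 3383), 147 without ecig 2, 4, 5 and 6, 1324 at 0.01 and 609 at a log2 fold change of at least 1. Without 1 library the counts stayed within 3678 to 4425 and 2113 to 3237 in these comparisons. Stricter thresholds reduce calls by construction, and what moved the counts under the other settings was not tested.

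Scaling moved the split of calls. In smoke versus air 61.3% of calls were higher, against 48.0% with RLE factors, 48.6% with DESeq2 and 39.1% with library size only. In e-cigarette versus air 48.3% became 29.7% with library size only, which shifted the median of all genes to -0.10, and in smoke versus e-cigarette 63.1% became 76.0%. The median of no gene list named in the text changed sign under RLE, library size only, DESeq2 or voom, except those of the NRF2 list, between -0.10 and 0.02, and of the xenobiotic metabolism list in smoke versus air, between -0.05 and 0.01.

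No pairing of the libraries by replicate number was seen. The labels do not state any, and a weak shared effect could be missed. Deviations of libraries with the same number correlated at -0.08 on average (-0.45 to 0.16 over 18 pairs), those with different numbers at 0.02, and 0 libraries matched their own number best. With the number as a replicate block 39, 3836 and 2386 genes were called, 28 of 37, 4 of 56 and 4 of 40 named calls were lost, and the list calls named in the text did not change.

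Of 43 lists, camera called 21 in smoke versus air, 22 in e-cigarette versus air and 14 in smoke versus e-cigarette. With an estimated correlation camera called 0 in each (lowest adjusted p 0.313, 0.369 and 0.516), and fry called 8, 22 and 12. With 4 or 5 covariates 14 lists each were called in e-cigarette versus air. The fibrillar matrix median in smoke versus air reversed to -0.21 with 4 and -0.14 with 5 covariates. The glandular acini medians were 0.14 in smoke versus air and 0.01 in e-cigarette versus air with 5 covariates, 1 of which is that list. The Thyroid, Fast skeletal muscle and Cartilage lists likewise lost their calls in e-cigarette versus air with scores made from them, and the Cartilage list also without air 4, 5 and 6. The overlap of calls was 554 with DESeq2, 29 as the median with split air libraries, and 356, 91, 35, 76, 79, 59, 46 and 51 without air 2, air 4, air 5, air 6, smoke 3, smoke 4, smoke 5 and smoke 6.

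Genes reversed by covariates, as log2 fold changes, were these. In e-cigarette versus air with 4 covariates: Rhcg 2.61, Pth 6.83, Gcm2 2.82, Sycp2l 3.58, Cryba2 1.46 and Ckm -0.04. With the thyroid score: Rhcg 3.71, Pth 3.28, Gcm2 3.71, Spink8 0.42, Sycp2l 3.65 and Cryba2 0.87. With 5 covariates: Smr2 -0.18, Csn3 -0.41, Lpo -0.39, Rhcg 2.22, Pth 7.87, Gcm2 2.29, Sycp2l 4.28, Mcoln3 0.70, Cryba2 1.81, Ckm -0.03 and Chrnd -0.11. In smoke versus e-cigarette with 4 covariates: Pth -3.25, Gcm2 -2.09, Sycp2l -1.89 and Calcoco2 0.06. With the thyroid score: Pth -3.81, Gcm2 -3.14, Spink8 -0.75 and Sycp2l -3.38. With 5 covariates: Pth -1.66 and Calcoco2 0.05. None of these reversed values passed the threshold.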

Other observations

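In e-cigarette versus air, the laminin chain Lamb3 (-0.88, adjusted p = 2.78e-04), the adhesion receptor Icam1 (-1.06, adjusted p = 1.14e-04) and the matrix glycoprotein Tnc (-1.24, adjusted p = 1.78e-05) fell. The metallothioneins Mt1 and Mt2 fell by 1.77 each, Mt1 from 288 ± 59.5 to 84.7 ± 22.4 CPM. Gdf15, a secreted stress signal, fell from 13.8 ± 7.10 to 0.908 ± 0.852 CPM (-3.89, SE 0.56, adjusted p = 9.67e-05) and Sesn2 by 1.18. Air 3 had the highest Lamb3 and Sesn2 of its group, and each of these calls held in all 18 fits without 1 library. Without ecig 2, 4, 5 and 6 Lamb3 (-0.57, adjusted p = 0.0907), Icam1 (-0.91, 0.0527) and Mt2 (-1.51, 0.0561) were no longer called. None of these genes was called with the thyroid score as covariate, and over 34 alternatives the adjusted p ranged up to 0.785 for Lamb3, 0.516 for Icam1 and 0.476 for Mt2, from 9.38e-07, 4.04e-08 and 6.88e-08. Basal epithelium genes as a list did not pass (5 rose and 4 fell among 20, median 0.25, camera adjusted p = 0.499).

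In the same comparison the B cell chemokine Cxcl13 fell from 30.1 ± 6.15 to 5.13 ± 2.05 CPM (-2.55, SE 0.23, adjusted p = 2.11e-06), the kinase Lck of T cells by 2.08 (adjusted p = 1.96e-05) and the B cell receptor chain Cd79b by 2.29 (adjusted p = 1.45e-04). With the thyroid score as covariate Cxcl13 was at -1.73 (SE 0.36, adjusted p = 0.145), Lck at -1.12 (SE 0.44, 0.457) and Cd79b at -0.57 (SE 0.53, 0.844), each the highest adjusted p of 34 alternatives, and the lowest were 3.63e-26, 1.89e-11 and 3.29e-09. As lists these cells did not pass camera. Of 9 B and plasma cell genes 3 fell (median -0.55, camera adjusted p = 0.0779, fry adjusted p = 0.00420), and of 13 T and NK cell genes 2 fell (median -0.10, camera adjusted p = 0.294, fry adjusted p = 0.0329). The B and plasma cell list passed in 5 of 27 alternatives, among them the fit without air 6 (-0.64, adjusted p = 0.0486, range 0.00420 to 0.557). The muscle-type nicotinic receptor subunits Chrna1 (0.86), Chrnd (0.83) and Chrne (0.97) rose beside the skeletal muscle genes. Of 8 nicotinic receptor genes 4 rose, with 5 higher and 1 lower adjusted over the list alone (median 0.77, camera adjusted p = 0.0240, adjusted p = 0.369 with an estimated correlation). That median was 0.22 with 4 composition covariates and 0.47 without air 4, 5 and 6, and the list was not called in either. It was called in 22 of 27 alternatives.

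The split counts and the thyroid slope were planned tests. The other tests of this part were chosen after the result was seen. With only 2 groups fitted and 100 splits of the 12 libraries, 1 split, the real one, called as many genes in each comparison. The real counts were 109, 3607 and 3455 in smoke versus air, e-cigarette versus air and smoke versus e-cigarette, and the highest other counts 81, 7 and 263.

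Low thyroid and parathyroid transcripts accompany the 4406 calls in e-cigarette versus air. Less thyroid tissue in the e-cigarette samples is consistent with Tg and Calca, made by different cells, varying together over the 6 e-cigarette libraries (r = 0.98, exact p = 0.00139, rho 1.00). Lower hormone synthesis in unchanged follicles would leave the C-cell gene Calca as it was, and Calca was at -4.42. Over 4393 called genes outside the Thyroid list, those that rose with the thyroid score within the e-cigarette group were lower there than in air (r = -0.66, exact one-sided p = 0.0222 over 720 orders). Over all tested genes outside that list r was -0.48. Part of these calls may thus follow the thyroid share or another share that varies with it. The muscle score ran opposite to the thyroid score within that group. It was 1.78 and 1.27 in ecig 4 and 5 (thyroid -2.14 and -2.03) and 0.59 and 0.44 in ecig 1 and 3 (thyroid -0.17 and -0.22). The slope therefore cannot tell these 2 shares apart. Whether dissection or exposure removed the thyroid tissue was not tested. Without ecig 2, 4, 5 and 6, Cd74 (-1.04), Top2a (1.29) and Cxcl13 (-1.98) were among the 24 of 56 named calls that were kept. The libraries left, ecig 1 and 3, were low in thyroid transcripts too (Tg at -1.41, Calca at -2.95). That fit therefore cannot separate these genes from the thyroid share. With the thyroid score as covariate Cd74 (-1.38), Top2a (1.81) and Cxcl13 (-1.73, a smaller fold) were not called, and why was not tested.

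Heat shock transcripts were lower than air in both exposed groups. A single high air library does not account for this in smoke versus air, since 9 members were called without air 3. In e-cigarette versus air the list lost its call without air 1 (camera adjusted p = 0.101) or air 3 (0.0714). With scores of muscle, cartilage, thyroid and fat as covariates the smoke versus air median did not shrink (-0.76, against -0.49). That goes against these shares as the scores measure them. The scores differ between the groups and that fit called 6 genes, so it cannot exclude the shares. Dnaja1 lost its call there with a larger SE (-1.32, SE 0.17, became -1.33, SE 0.27, adjusted p = 0.0794). Handling of the air samples at collection could lower or raise immediate early genes as well, whose median was -0.87, and with 1 air group it cannot be told apart from exposure.

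Lipogenic transcripts were higher in smoke than in air. Smoke 5 alone does not account for the pattern, since 4 of the 6 called genes (Fasn, Scd1, Acaca, Acly, Insig1 and Nsdhl) passed without it, but Fasn did not (1.63, adjusted p = 0.0605). More adipocytes in the smoke samples cannot be told apart from a change within cells, since all 28 tested lipogenesis genes, which went both ways, averaged 0.32 and 18 other adipocyte markers 0.43 (difference -0.11, exact p = 0.303 over 924 splits). Fasn (2.03) and Scd1 (1.58) lay above that marker mean but were picked because they were called, and with 4 composition covariates the fold of Fasn shrank from 2.03 (SE 0.41) to 0.52 (SE 0.37) and its call ended. Feeding and time of collection, which could act on these genes as well, are not given in the sources used here.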
